A study of Homo sapiens with 16 samples.

How the data were processed

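Human K562 cells were treated with vehicle or a TOP2 poison, TOP2A was immunocaptured from sonicated lysates, and the bound DNA was released and sequenced, per the labels' protocols. Some libraries were amplified before library preparation and others were not, and the sample descriptions tie only amplified libraries to the lists of 4 treatments. No description names the mitoxantrone list, which was tied to its 1 library by treatment. Another p-benzoquinone library is called amplified in its description but not in its title and source, by which it was grouped. Bowtie2 2.1.0, SAMtools 0.1.19 and hg38 are named in the submitters' processing notes. The region caller and its thresholds are not given in the sources used here. The authors deposited 1 union list per treatment with a start and an end per region. The score of each region, as the authors deposited it, has no stated unit; its steps are those of a normalized read number, and a region with several values was read as joined from several library components. Only the deposited mitoxantrone list also carried an input signal, a log2 value and, for some regions, a p-value. In it the log2 value equalled the log2 of the ratio of the deposited treated to input values, its lowest was 4.00, and a p-value was given only where the deposited input signal was 0, in 45568 of 202926 regions.

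Regions were kept on chromosomes 1 to 22, X and Y; other sequences held at most 0.0659% of a list. The genistein list held 10561 entries overlapping their neighbour and 43 exact duplicates, which were joined. The callable genome was set as 100 kb bins with a region in any list, 2763 Mb in all. Genes came from the RefSeq table of GRCh38.p14, which has positions but neither strand nor exons, so the planned start-site window, exons and introns were replaced by both gene ends with 1 kb on each side. Of 20033 protein-coding genes, 18969 had at least 50% of their window callable. The window was the gene body with 2 kb on each side. All 401 entries of the 15 gene lists matched the table, 1 through an older symbol, and 394 were measured.

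Overlap was 1 bp or more and was set against 1000 circular shifts of the list along each chromosome. Intervals of covered shares and log2 enrichment came from 1000 bootstrap draws of 631 blocks of 5 Mb. Gene cover is the covered share of the window over the genome mean. Log2 ratios over DMSO used a pseudocount of 0.1, which understates the change of low genes. List medians were set against 10000 random lists matched on gene length in 10 bins, with ties at mid-rank, as a description with no p-value. Ratios of CCR numbers were scaled to list size with exact binomial 95% intervals. PCR reads without molecular identifiers are not independent molecules, so such intervals cover counting error only. The depth of each library is unknown, because the lists hold called regions; the steps put the lowest region kept at 8 to 12 reads.

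The named genes were fixed by rule before the data were examined. They are the 5 highest and 5 lowest log2 ratios per poison among genes with at least 10 CCRs in either list, and the 5 genes with the highest cover per list among those with at least 5 CCRs. All measured leukaemia translocation genes and the 3 genes of each other list with the highest mean cover over the 5 treatments complete the rule. Some genes that the rule names are not reported here. The overlap, Jaccard, enrichment and gene-list comparisons, and most alternatives, were also fixed then. Library parts were found after seeing the data. The number of steps was set by hand per list, and the search then took the steps that explained most values. Of low values 99.2% to 100.0% fell on the steps found, against 11.1% to 35.7% expected by chance. Values that fitted no step or several, or were 30 or more, were left out of the parts. They made up 21.7% of the values in DMSO, 32.7% in etoposide, 26.8% in genistein, 13.6% in mitoxantrone and 22.0% in p-benzoquinone. With the number of steps set for it, DMSO has 1 fine part although its labels name 3 amplified libraries. In that part 2068 neighbouring components lay under 200 bp apart, against at most 55 in any other part. It may therefore pool libraries that share a step.

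Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The steps were tested on simulated data. With 182582 simulated regions and no planted overlap the fold was 1.01, and a planted 5% gave an excess of 4.81%. A simulated log2 difference of 0.313 at gene ends was recovered as 0.309. Its 95% interval, 0.306 to 0.312, lay just below the simulated value. With 100 simulated lists of 20 genes over 18969 genes, 6% were outside the central 95% with no effect and 97% at a 2-fold effect. Of 20000 simulated values from known steps, 81.7% were assigned and 99.99% of those correctly. The simulated steps lay far apart, and close ones such as the 0.3587 and 0.3389 of the genistein parts were not simulated.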

Results

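The data were 5 lists of TOP2A cleavage cluster regions in K562, a human chronic myeloid leukaemia line that carries the BCR-ABL1 fusion. Such a region (CCR) is a short stretch where DNA held in covalent TOP2A cleavage complexes piled up after immunocapture of the enzyme. DNA topoisomerase II alpha (TOP2A) cuts both strands to let another duplex pass, and TOP2 poisons leave the enzyme trapped on the cut DNA. The lists covered 4 poisons and the vehicle: 25 µM etoposide, 50 µM genistein and 2 µM mitoxantrone for 1 h, 8 µM p-benzoquinone for 4 h, and 0.05% DMSO. Exposure to p-benzoquinone was longer than to the other poisons, so times differ wherever it is set beside them. No exposure time is recorded for the DMSO libraries, so whether times match is unknown wherever a poison is set against DMSO. The labels name 16 libraries, of which 14 came from treated or vehicle cells and 2 from input DNA. Pre-amplified libraries numbered 3 for DMSO, 3 for etoposide, 2 for genistein, 1 for mitoxantrone and 2 for p-benzoquinone. The authors pooled each treatment into 1 list, so there is no replicate value per region and no p-value between treatments.

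The first comparison asks how much of the genome carried CCRs under each treatment. Genistein had the most CCRs, 415215 on chromosomes 1 to 22, X and Y, which was 1.34 times the DMSO number of 310038. The p-benzoquinone list held 359249 CCRs, 1.16 times the DMSO number. As deposited, the etoposide and mitoxantrone lists were shorter than the vehicle list, with 182582 and 202865 CCRs, or 0.589 and 0.654 times the DMSO number. Covered bases made up 1.86% of the callable genome in DMSO (95% interval 1.83 to 1.88). The shares were 1.11% for etoposide (1.09 to 1.12), 2.59% for genistein (2.55 to 2.62), 1.28% for mitoxantrone (1.26 to 1.29) and 2.23% for p-benzoquinone (2.17 to 2.29). Median CCR width lay between 150 and 160 bp in every list. These intervals come from a bootstrap of 5 Mb blocks and cover unevenness along the genome, not differences between cultures. CCR number also follows the lowest value each list kept, which was 1.84 in DMSO, 1.82 in etoposide and p-benzoquinone, 3.72 in genistein and 3.87 in mitoxantrone. With only values of at least 4 kept, the numbers were 209960 for DMSO, 148223 for etoposide, 409454 for genistein, 199894 for mitoxantrone and 223052 for p-benzoquinone, or 0.706, 1.95, 0.952 and 1.06 times DMSO for the 4 poisons. So mitoxantrone was then about level with the vehicle. List size can also follow the number of pooled libraries. The 1 mitoxantrone library part, as defined by value step further on, held 175405 components against 128540 and 120305 in the DMSO parts. The DMSO part of 120305 may pool more than 1 library, and the parts leave out 13.6% of mitoxantrone and 21.7% of DMSO values. These are therefore not numbers per library.

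**Figure D1:**
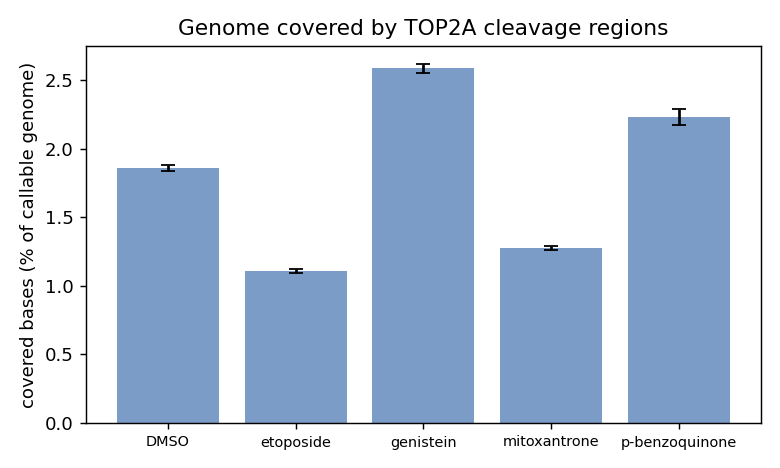
Bars give the percent of the callable genome covered by CCRs in each of the 5 lists, with error bars for the 95% block bootstrap interval. Genistein is highest at 2.59% and etoposide lowest at 1.11%.

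The second comparison asks whether the poisons trapped TOP2A at the places that were already cut in vehicle-treated cells. Poison CCRs overlapped DMSO CCRs more often than shifted lists did, although few were shared. Of the etoposide CCRs 8.39% overlapped a DMSO CCR by at least 1 bp, as did 6.79% for genistein, 7.06% for mitoxantrone and 7.88% for p-benzoquinone. Each share was above the level of lists shifted along the chromosomes, by 2.26-fold for etoposide, 1.80-fold for genistein, 1.86-fold for mitoxantrone and 2.08-fold for p-benzoquinone. The one-sided permutation p was 0.001 for each poison, the smallest that 1000 shifts can give. Low shares were also found within a treatment. Of the CCRs of the larger library part 2.81% overlapped the other part in DMSO, 3.52% in genistein and 1.61% in p-benzoquinone, and of the smaller part 3.03%, 3.72% and 6.67%. Among the 3 etoposide parts the shares ran from 0.191% to 2.96%. Parts are smaller than whole lists and leave out the highest values and those that fit several steps, which lowers such shares.

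Every pair of lists shared more bases than shifted copies did. The Jaccard index, shared over combined covered bases, ran from 0.0145 for p-benzoquinone with mitoxantrone to 0.0256 for p-benzoquinone with DMSO. Over chance it was highest for etoposide with DMSO, at 2.81-fold, and lowest for p-benzoquinone with genistein, at 1.75-fold. The permutation p was 0.001 for each of the 10 pairs. After merging the 5 lists, 1134482 of 1291451 regions, or 87.8%, came from 1 list. Regions present in 4 lists numbered 1529 against 201 on average in shifted lists, and those present in all 5 numbered 69 against 4.17. Merging joined regions that overlapped in a chain, in shifted lists too. The lists present in a merged region therefore need not share a base of it.

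Of the 69 regions in all 5 lists, 38 touched a protein-coding gene. They included SPAG9 (chromosome 17, 50963230 to 50963918, hg38), which encodes a JNK scaffold protein, and EHMT1 (chromosome 9, 137642154 to 137642505), which encodes a histone methyltransferase. Others were in PIAS2 on chromosome 18, BCAS4 on chromosome 20, RIMS3 on chromosome 1, the fragile-site gene WWOX on chromosome 16, and BCR on chromosome 22. The region with the highest floor over the 5 lists lay outside protein-coding genes, on chromosome 10 from 125291068 to 125291784, where the lowest of its 5 values was 9.9. These genes were chosen after their values were seen.

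Nearly all low values were whole multiples of 1 to 3 steps, a number set per list, as scaled whole reads are. This split every list but mitoxantrone, for which 1 step was set, into library parts. Steps fell into a coarse class (0.324 to 0.359) and a fine class (0.228 to 0.247). DMSO and etoposide held both classes, genistein and mitoxantrone only coarse parts, and p-benzoquinone only fine parts. The lowest Jaccard folds of whole lists, p-benzoquinone with genistein (1.75) and with mitoxantrone (1.76), were thus between lists sharing no class. The highest, etoposide with DMSO (2.81), was between the lists holding both, so that order cannot be read as likeness of treatments alone. CCRs of different treatments overlapped 1.95-fold to 2.30-fold over chance between coarse parts and 2.47-fold to 4.16-fold between fine parts. Parts of the same treatment but different class overlapped 1.35-fold to 2.00-fold (median 1.61). Those that shared neither treatment nor class overlapped about as much, at 1.48-fold to 2.06-fold (median 1.72). The 2 genistein parts overlapped each other 1.96-fold and the 2 p-benzoquinone parts 2.36-fold, while the 2 fine etoposide parts reached 11.8-fold. By Jaccard index the folds of parts of the same treatment but different class were 4.29 to 6.50, and that of the p-benzoquinone parts was 7.74. There a region joined from several libraries counted at its full length in each part, which raises the index. The genistein entries, which were deposited unjoined, gave 2.40, and coarse parts of different treatments 2.40 to 2.89. Which labelled library gave which part was not assigned.

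**Figure D2:**
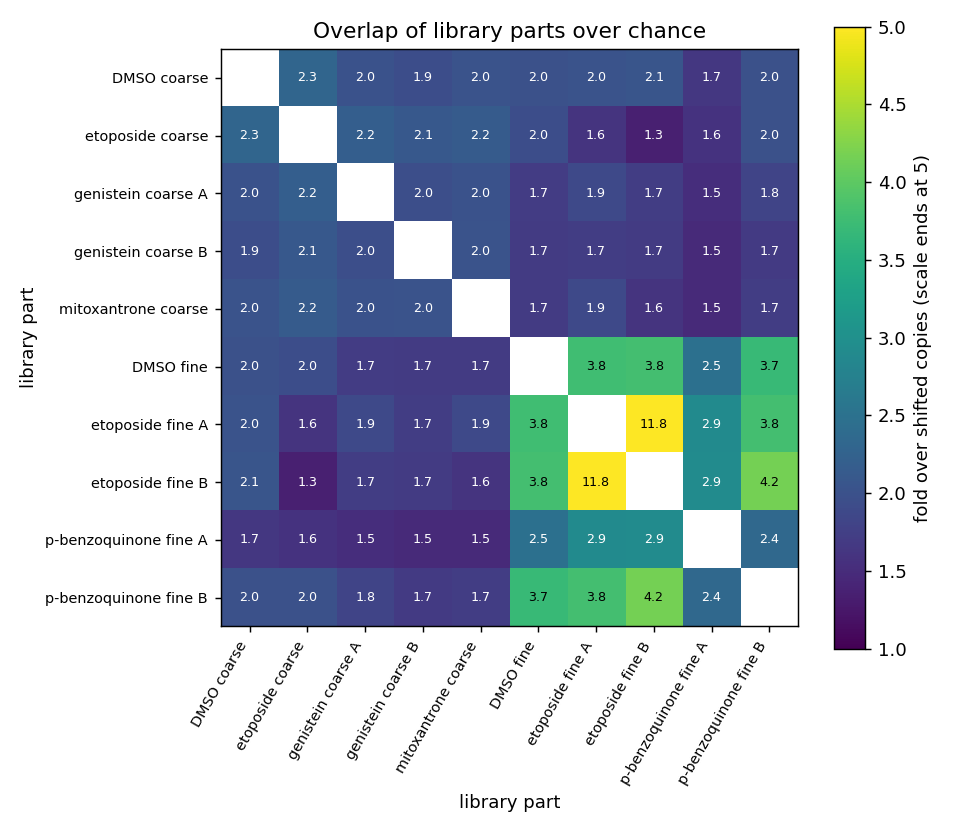
Each cell gives the overlap of a pair of library parts as a fold over shifted copies, with parts ordered by step class; the colour scale ends at 5. Fine parts of different treatments reach 2.47 to 4.16, above the 1.95 to 2.30 of coarse parts.

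The third comparison asks where CCRs lay relative to genes. Gene bodies held slightly more covered bases than the genome share in every list. Protein-coding gene bodies make up 44.6% of the callable genome and held 47.0% of DMSO-covered bases, 46.0% for etoposide, 45.5% for genistein, 45.5% for mitoxantrone and 49.4% for p-benzoquinone. The ends of protein-coding genes, taken as 1 kb on each side of both ends, were most covered under p-benzoquinone, at 1.29 times the genome share. The other values were 1.05 for DMSO, 0.955 for etoposide, 0.877 for genistein and 0.869 for mitoxantrone. In log2 terms the difference from DMSO at gene ends was 0.30 for p-benzoquinone (95% interval 0.26 to 0.34), -0.13 for etoposide (-0.18 to -0.078), -0.26 for genistein (-0.31 to -0.21) and -0.27 for mitoxantrone (-0.33 to -0.21).

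Within the step classes these differences were smaller. Both genistein parts stayed below the coarse DMSO part, at -0.12 (-0.20 to -0.052) and -0.15 (-0.23 to -0.073), and so did mitoxantrone at -0.12 (-0.19 to -0.043). The 3 etoposide parts gave -0.032 (-0.11 to 0.050), -0.074 (-0.20 to 0.052) and 0.0080 (-0.15 to 0.16), with intervals that included 0. With 5 kb on each side they gave -0.072 (-0.11 to -0.037), -0.074 (-0.14 to -0.016) and 0.015 (-0.058 to 0.084). The larger p-benzoquinone part was 0.15 above the fine DMSO part (0.093 to 0.22) and the smaller part was at -0.065 (-0.15 to 0.026). Those 2 p-benzoquinone parts differed from each other by -0.22 (-0.30 to -0.14). The fine and coarse parts of DMSO itself differed by 0.29 (0.21 to 0.37).

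**Figure D3:**
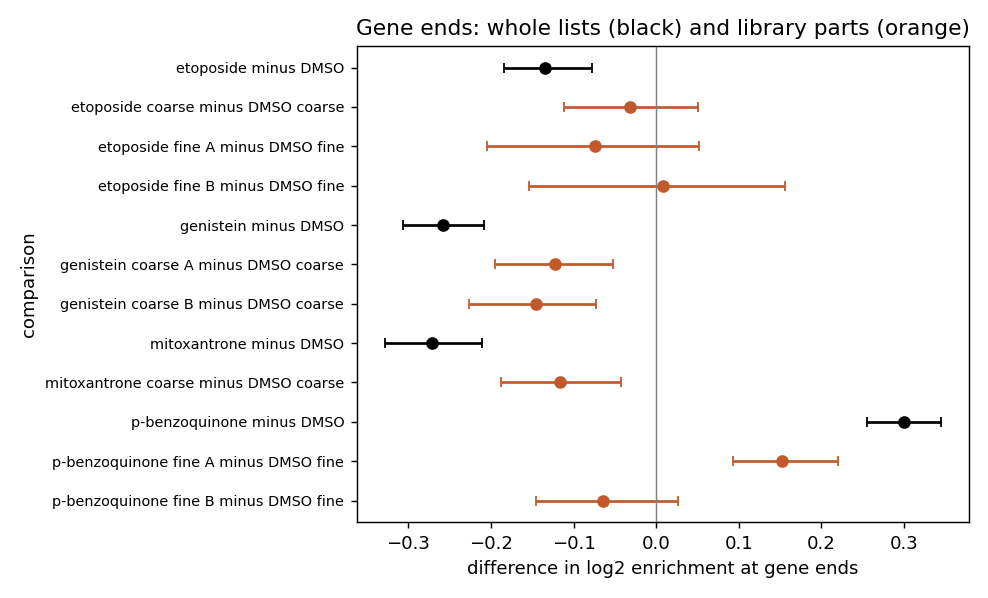
Points give the difference in log2 enrichment at the ends of protein-coding genes between a poison and DMSO, with 95% block bootstrap intervals, for whole lists in black and library parts in orange. The whole p-benzoquinone list lies at 0.30, while its 2 parts lie at 0.15 and -0.065.

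Chromosomes and gene-dense stretches also differed between the lists. On chromosome 19, the most gene-dense human chromosome, CCR coverage over DMSO was 0.32 higher in log2 terms for p-benzoquinone (0.20 to 0.42) and the genistein value was -0.35 (-0.44 to -0.24). Library parts of 1 class lay closer: coverage there was 1.09 times the genome mean in the fine DMSO part and 1.14 and 1.02 in the p-benzoquinone parts, and 0.772 in the coarse DMSO part and 0.713 in each genistein part. Chromosome 13 went the other way, with -0.44 for p-benzoquinone (-0.55 to -0.32) and 0.17 for etoposide (0.10 to 0.23). On the X chromosome the values were -0.42 for p-benzoquinone (-0.49 to -0.35) and 0.20 for etoposide (0.15 to 0.25). The fine part of DMSO covered the X at 0.657 of its genome mean and the coarse part at 0.931, beside 0.602 and 0.622 in the p-benzoquinone parts and 1.02 in the coarse etoposide part. On chromosome 13 the fine DMSO part was at 0.674 and the p-benzoquinone parts at 0.631 and 0.668. Among genes in length bin 2 of 10 (3.32 to 6.97 kb), mean coverage was 1.47 times the genome mean for p-benzoquinone, 1.10 for DMSO and 0.833 for mitoxantrone. The fine DMSO part was at 1.31 and the coarse part at 0.987, and the p-benzoquinone parts were at 1.49 and 1.33.

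The fourth comparison asks whether the 15 fixed gene groups carried more or fewer CCRs than length-matched genes. CCR numbers of single genes are unscaled unless a ratio is given, and the poison lists held 0.589 to 1.34 times the DMSO number. T-cell and B-cell marker genes lay above most random lists in DMSO, etoposide and p-benzoquinone. Their median cover was 1.43 times the genome mean in DMSO (percentile 98.7 of 10000 random lists), 1.32 under etoposide (98.2) and 1.68 under p-benzoquinone (98.2). In DMSO 15 of the 20 genes lay above the genome mean. CD79A, part of the B-cell receptor, had 4 CCRs in DMSO, and CD3D, part of the T-cell receptor complex, had 3 in DMSO and 7 under p-benzoquinone. The costimulatory receptor gene CD28 had 7 CCRs in DMSO and 9 under p-benzoquinone. With at least 4 required of every value, the percentiles were 95.3, 83.8 and 92.4, inside the central 95% of random lists. By list mean within DMSO, the coarse part lay at percentile 92.2 and the fine part at 99.9; the larger p-benzoquinone part was at 98.6 and the smaller at 66.2. The whole list means were at 99.7 in DMSO and under p-benzoquinone. The etoposide list mean was at 89.4 and its parts at 56.3, 53.6 and 94.7, all inside the central 95%.

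DNA topoisomerase and repair genes had a median of 0.702 times the genome mean in DMSO, at percentile 0.8, with 6 of 20 genes above the mean. Their log2 ratio over DMSO had a median of 0.53 for etoposide (percentile 99.8) and 0.45 for genistein (99.6). Both ratios use the same low DMSO values, so they are not independent. The list mean for etoposide had the opposite sign, at -0.045 (percentile 70.6), while the genistein mean was 0.39 (97.7). For mitoxantrone the mean was 0.51 (99.5) and the median 0.33 (97.4), so only the mean lay outside the central 95%. With values of at least 4 the percentiles were 5.32 in DMSO, 96.8 for the etoposide ratio and 98.4 for the genistein ratio. XRCC5, which encodes the Ku80 end-binding protein, had 11 CCRs in DMSO, 11 under etoposide and 23 under genistein. The nuclease gene MRE11 had 9, 7 and 26. TDP2, whose product removes TOP2 adducts from DNA ends, had 2, 2 and 3.

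Erythroid and K562-expressed genes were low in the genistein list, with a median of 0.368 times the genome mean (percentile 1.04) and 6 of 22 genes above the mean. The list mean was at percentile 6.8, inside the central 95%, and within genistein it was 0.347 in the larger part (percentile 0.57) and 0.639 in the smaller (21.2). In the other lists this group lay between percentiles 38.8 and 85.8. The mitochondrial iron importer gene SLC25A37 had 11 CCRs in DMSO, 8 under genistein and 17 under p-benzoquinone, and LMO2, an erythroid transcription cofactor gene, had 9, 7 and 10. The fetal globin gene HBG1 had 1, 2 and 1. Hepatocyte marker genes were at percentile 98.5 for genistein (58.1 with gene bodies only), and their log2 ratio of etoposide over DMSO had a median of 0.54 (percentile 99.1, or 86.0 with values of at least 4). Their list means of cover were at 97.8 for genistein and 98.6 for etoposide. By list mean 1 part stood apart in each: the larger genistein part was at 1.71 (percentile 99.9) and the smaller at 0.873 (56.5), and the coarse etoposide part at percentile 99.7 with the fine parts at 27.6 and 62.2. FGA and FGG, which encode fibrinogen chains, each had 3 CCRs under etoposide against 3 and 2 in DMSO.

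Replication-dependent histone genes had a genistein median of 1.15 (percentile 99.9), which was 0 with the 2 kb flanks left out (percentile 50.0). Their list mean was at percentile 83.6 under genistein and, outside the central 95%, at 1.21 under mitoxantrone (98.4), where the median was 0. By list mean within parts they were at 99.7 in the fine and 3.83 in the coarse DMSO part, and at 10.1, 99.6 and 25.7 in the etoposide parts. Within genistein the larger part was at 28.05 and the smaller at 64.2. H3C3 had 2 CCRs in DMSO, etoposide, genistein and p-benzoquinone alike. Ribosomal protein genes, among the most transcribed of all, lay between percentiles 35.8 and 95.8, and RPL23A and RPL4 were among those with the highest mean cover. Housekeeping genes lay between 50.9 and 84.2, and GAPDH had 1 CCR in DMSO and 2 under etoposide. Immediate early genes had a log2 etoposide over DMSO median of 0.34 (percentile 97.6), which was at percentile 63.3 when CCRs were counted per kb. The mean ratio was at 89.4, and by mean cover the etoposide parts were at 58.6, 57.9 and 98.7, the last on 4 CCRs. EGR1 had 1 CCR in DMSO and 3 under etoposide, and ATF3 had 8 and 3. The p53 target genes, NRF2 targets, neuronal markers, keratinocyte genes, olfactory receptor genes and common fragile site genes had medians within the central 95% in every list and ratio. By list mean, neuronal markers were at 1.27 under mitoxantrone (percentile 97.9), just outside it. Of the fragile site genes, RBFOX1 (chromosome 16, 5239721 to 7713340) had 374 CCRs in DMSO and 409 under genistein, a ratio scaled to list size of 0.817 (counting interval 0.708 to 0.942). In all, 7 of 75 medians and 5 of 60 ratios lay outside the central 95%, where chance gives 0.75 of the 15 lists for each treatment.

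**Figure D4:**
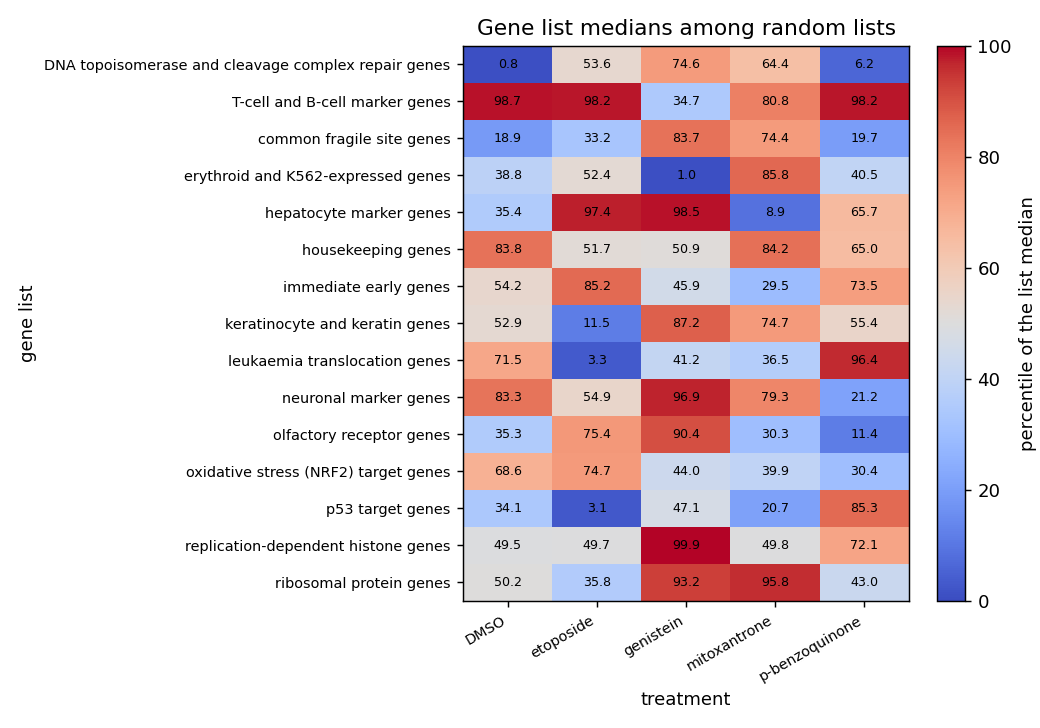
Cells give the percentile of each gene list's median cover among 10000 random lists matched on gene length, by treatment. T-cell and B-cell markers reach 98.7 in DMSO and the topoisomerase and repair genes 0.8.

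Leukaemia translocation genes, the partners in fusions seen after TOP2 poison therapy or in leukaemia generally, had a log2 p-benzoquinone over DMSO median of 0.37 (percentile 99.2; mean 0.43 at 99.4), with 19 of 24 genes above 0. The percentile was 93.8 when CCRs were counted per kb and 88.9 with values of at least 4. By list mean the larger p-benzoquinone part was at percentile 98.1, the smaller at 70.8 and the fine DMSO part at 59.2. MLLT1 had 19 CCRs under p-benzoquinone and 6 in DMSO, a scaled ratio of 2.73 (1.05 to 8.36). For RUNX1 the numbers were 55 and 35 (1.36, 0.872 to 2.13), and for RARA 14 and 8 (1.51, 0.591 to 4.16). TCF3 had 12 and 5 (2.07, 0.679 to 7.50), ETV6 53 and 36 (1.27, 0.817 to 2.00), and AFF1 29 and 24 (1.04, 0.586 to 1.87). Under etoposide NUP98 had 9 CCRs against 6 in DMSO (2.55, 0.810 to 8.70), while PML had 3 against 12 (0.425, 0.0769 to 1.57). MLLT3 had 26 under etoposide (1.38, 0.790 to 2.39) and 24 under p-benzoquinone (0.647, 0.365 to 1.13) against 32 in DMSO. CBFB had none under mitoxantrone against 9 in DMSO. MECOM, the longest of the group, had 96 in DMSO, 40 under etoposide (0.708, 0.477 to 1.03) and 113 under genistein (0.879, 0.664 to 1.17).

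KMT2A (chromosome 11, 118436492 to 118526832), the gene most often rearranged in leukaemia after TOP2 poisons, was covered 7.78 times the genome mean under p-benzoquinone. Its cover was 1.21 in DMSO, 0.96 under etoposide, 1.43 under genistein and 1.82 under mitoxantrone. The number of CCRs was not unusual, at 19 under p-benzoquinone and 15 in DMSO. A single region of 8288 bp (118505952 to 118514239) with a deposited value of 1816.82 held much of the covered length; without it the cover was 3.84. That region held the value of 1 library, although the list came from 2 amplified libraries; so did 96.0% of the 100 highest regions outside KMT2A. The widest p-benzoquinone region outside KMT2A was 1358 bp and the highest value there was 135.

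**Figure D5:**
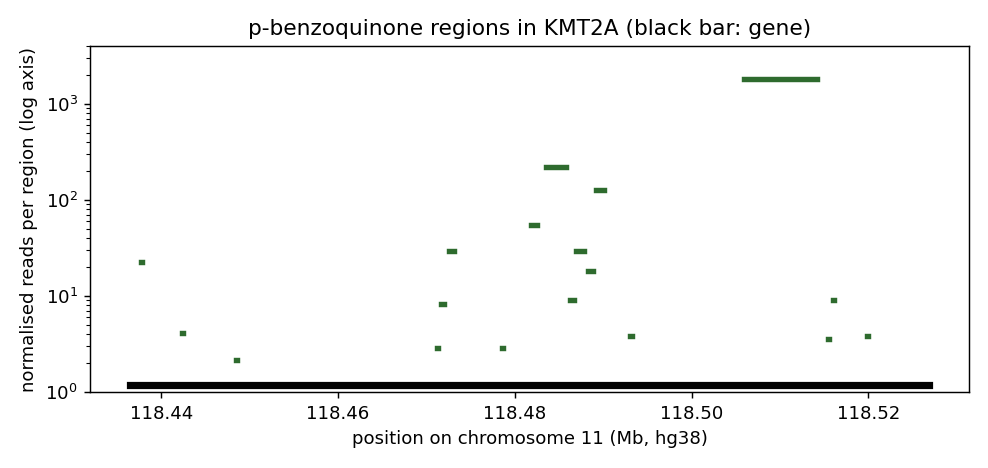
Horizontal lines mark each p-benzoquinone region in KMT2A at its highest deposited value (log axis) against position on chromosome 11, and the black bar marks the gene. The region from 118505952 to 118514239 stands at 1816.82; the 3 highest others, between 118481838 and 118490140, stand from 54.9 to 221.

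The fifth comparison gives single genes with the highest and lowest cover over DMSO. Among the 5 highest by cover under etoposide were ZNF277 (chromosome 7) and SLC30A7 (chromosome 1), each with 15 CCRs against 6, a scaled ratio of 4.25 (1.56 to 13.4). KIF18A, a mitotic kinesin gene, had 11 against 4 (4.67, 1.38 to 20.1), the autophagy gene RB1CC1 11 against 5, and BEST3 10 against 4; each of these kept the direction in 2 of 3 library parts. The lowest were SFT2D1, KRT80, PCDHGC3, WDR91 and TNFRSF10A, a TRAIL receptor gene, each listed with no etoposide CCR against 10 to 12 in DMSO.

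Under genistein BMP10, CD46 and BAG4 had 10 CCRs each and none in DMSO. Set against a floor of 3 CCRs and scaled to list size this was 2.49-fold, without the counting error of the 10. POLI, a translesion polymerase gene, had 16 against 1 (11.9, 1.86 to 501) and C8orf88 13 against 1. PHF19, a Polycomb-associated gene, and the chloride channel gene CLCN1 had none against 12 and 11. PTPN23 and HIF3A had 1 each against 10, and SLC6A9 had 3 against 13. Genistein has no fine part, yet 10 of the DMSO CCRs of CLCN1, 9 of SLC6A9 and 8 each of PHF19 and HIF3A came from the fine part. Against the coarse part neither genistein part kept the direction for CLCN1, and 1 of 2 did for SLC6A9.

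Under mitoxantrone ANKHD1 had 15 CCRs against 2 (11.5, 2.67 to 103), SLC49A4 12 against 3, URI1 11 against 3 and ZCCHC2 10 against 2. The cohesin loader gene MAU2, the kinase gene MKNK1, LNP1, the adenosine receptor gene ADORA1 and GEMIN5 had none against 10 to 12. For MAU2 and MKNK1 7 of the DMSO CCRs came from the fine part, a class that mitoxantrone lacks.

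Under p-benzoquinone CHRNB3, a nicotinic receptor subunit gene, had 15 against 1 (12.9, 1.99 to 545), and KCP and MGAT3 had 13 against 1. KLHDC8A and TRAF7 had 10 and none in DMSO, 2.88-fold against a floor of 3 CCRs, again without the counting error of the 10. TMC3 had 1 against 14 (0.0616, 0.0015 to 0.405), RXYLT1 1 against 10, and CWF19L1, RADX and CYSLTR2 2 against 12, 12 and 11. Here the coarse part, a class that p-benzoquinone lacks, gave 9 of the DMSO CCRs of RADX and 6 each of CWF19L1 and CYSLTR2. RADX and KLHDC8A kept the direction in 1 of 2 parts. Agreement of parts is partly built in for genes chosen as extremes, so only its absence is given. These genes are the extremes of 4381 to 5769 genes, and their intervals cover counting error only.

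The genes with the densest cover among those with at least 5 CCRs were MEA1, ATP6V0E2, KLHL38, DEFB118 and LOC124900214 in DMSO, with MEA1 at 6.54 times the genome mean. Under etoposide FBL, the fibrillarin gene, led at 8.13, followed by CSN2, KLK5, BNIP1 and the gluconeogenesis gene PCK1. Among the highest under genistein were SNRPB at 5.21, BMP10, SRPK3 and TIFAB. CALHM3 led under mitoxantrone at 6.11, followed by WNT8B, CNIH1, LGALS12 and PGLYRP4. KNCN led under p-benzoquinone at 9.45, followed by TEX51, the keratin gene KRT13, TMEM151B and POLDIP2.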

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

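The tests of library parts, of the KMT2A region and of input at BCR and ABL1 were chosen after the result was seen, and that of a common lowest value was chosen after seeing the data.

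The deposited input values of the mitoxantrone list, which no comparison above used, were raised at the BCR stretch. Over the BCR and ABL1 stretches together, the median input per base of the 11 mitoxantrone regions was 4.81 times that of the other 202854 regions (95% interval 1.82 to 11.3). The 8 regions of the BCR stretch carried this at 7.37 times (1.97 to 20.1). The 3 ABL1 regions were at 1.82 times (0.963 to 4.81), too few to tell. CCRs were few in both stretches. The BCR stretch (chromosome 22, 22180509 to 23318037) spans 1138 kb and runs well beyond the BCR gene, while the ABL1 stretch spans 175 kb. The BCR stretch held 0.337 of the genome density in DMSO (0.244 to 0.454), 0.105 under genistein and 0.0958 under mitoxantrone. ABL1 held 0.357 in DMSO. K562 carries extra copies of the fused segments, and a threshold over input may hide regions there. The raised input over the BCR stretch as a whole goes with this. Lower TOP2A cleavage there cannot be told apart, because all 11 regions had input above 0, and regions with input above 0 had log2 ratios of treated over input of 4.00 or more, a floor which ties their treated values to the input. The treated values there were 3.50 times those of all other regions. Among regions with input above 0 only they were 3.34 times those elsewhere, and the input of the BCR stretch was 5.08 times (1.36 to 13.8).

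The difference between poisons and DMSO at gene ends depended on which library parts were compared. For etoposide class, library and treatment cannot be told apart: with 1 kb on each side the part nearest 0 was at 0.0080 and all 3 intervals included 0, but with 5 kb the intervals of 2 parts lay below 0. For genistein and mitoxantrone the step class alone is argued against, since the values nearest 0 were -0.12 and -0.12 with intervals below 0. A treatment effect and a difference between single libraries both stay open, as does a shift over gene-dense stretches as a whole. For p-benzoquinone the parts lay on opposite sides of 0, one at -0.065, so class, library and treatment cannot be told apart. With at least 4 in every list the p-benzoquinone difference was 0.41 (0.36 to 0.47), so a common lowest value did not remove it. That floor lies near the lowest value of the coarse DMSO part (3.72) and far above that of the fine part (1.84). It therefore changes the class mix of the DMSO list, and it was not run within the fine class. Low values kept in some lists only thus cannot be told apart from class for p-benzoquinone.

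The wide KMT2A region under p-benzoquinone stood at 13.4 times the highest value outside the gene in that list. It held 1 library value, while the list was made from 2 amplified libraries. Of the 100 highest regions outside KMT2A 96.0% also held 1 value, so this count alone does not decide. If values stand for libraries, the other library had no called region in the span, and a signal of like size in both was not seen. With depth and thresholds per library unknown, DNA present in 1 library only and a p-benzoquinone effect shared by its libraries cannot be told apart. The same span held 3 regions in DMSO with values up to 5.07, 2 under genistein, 2 under mitoxantrone and 0 under etoposide. Elsewhere in KMT2A 2 p-benzoquinone regions held values of 2 libraries, the higher at 127, and whether the DNA of the wide region came from the cells was not tested.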

How the results depend on the processing

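No paired analysis was possible because each treatment is 1 pooled list whose columns carry no replicate number; library parts, which were not tied to labelled libraries, were compared instead. Start-site windows, exons and introns, non-N bases, GC-matched backgrounds and GC-matched random lists were not run, since no strand, exon or sequence table was used here. Alternatives chosen after seeing the data were the common lowest value of 4, local shifts, gene ends, library parts, list means, genistein entries as deposited and leaving out the widest KMT2A region. The 4 overlap folds with DMSO kept direction and significance in all 28 alternatives, between 1.75 and 2.95, as did the 10 Jaccard folds in 40, between 1.68 and 2.81. The higher-scoring 50% of each list held 155179 CCRs for DMSO, 91640 for etoposide, 210124 for genistein, 101941 for mitoxantrone and 182916 for p-benzoquinone, by construction. A value of at least 4 in every list left 223052 CCRs for p-benzoquinone, 209960 for DMSO and 199894 for mitoxantrone. DMSO enrichment at gene ends turned to -0.049 in the higher-scoring 50% and was 0.0079 with values of at least 4. Within library parts, etoposide minus DMSO at gene ends was -0.032, -0.074 and 0.0080, and at gene bodies -0.0066 for the smallest part. The smaller p-benzoquinone part gave -0.065 at gene ends and 0.010 at gene bodies. The cause of these changes was not tested. Gene list medians outside the central 95% of random lists numbered 7 of 75 and were 0 in the higher-scoring 50% and 3 with values of at least 4; the log2 ratios numbered 5 of 60 and were 3 by CCRs per kb, all 3 among the 5. Histone genes under genistein had a median of 0 with gene bodies only and 0 in the higher-scoring 50%, at percentiles 50.0 and 49.8. All 40 genes chosen by rule for their ratio to DMSO kept their direction in 160 alternatives. This is partly built in, since they are extremes of that ratio and a changed pseudocount cannot turn a direction. Of the alternatives 67 moved the log2 value by 0.5 or more. These included 40 of 40 with a pseudocount of 1, which shrinks ratios by construction, and 18 in the higher-scoring 50%. With 10 to 16 CCRs in the higher list of each gene, counting error limits single-gene ratios.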

Other observations

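Homozygous loss of the CDKN2A region is known in K562, and a stretch chosen after the data were seen runs from IFNB1 to DMRTA1 on 9p21 (chromosome 9, 21077104 to 22455740). It held 3 CCRs in DMSO, 4 under etoposide, 13 under genistein, 5 under mitoxantrone and 0 under p-benzoquinone. As a share of the genome density this was 0.0194 in DMSO (0.004 to 0.0567), 0.0439 under etoposide, 0.0628 under genistein (0.0334 to 0.107) and 0.0494 under mitoxantrone.

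Merged regions, joined in chains as above, that held CCRs of all 4 poisons and none of DMSO numbered 223, against 35.3 on average in shifted lists. In the DMSO list 7509 regions, or 2.42%, joined components from 2 or more libraries, as did 0.997% for etoposide and 1.60% for p-benzoquinone, while 2.48% of the deposited genistein entries overlapped their neighbour. By list mean, topoisomerase and repair genes lay at percentile 1.28 in the coarse DMSO part, 0.82 in the fine DMSO part, and 1.88 and 1.86 in the p-benzoquinone parts; these tests of library parts were chosen after the result was seen.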
